A study of Homo sapiens with 9 samples.

How the data were processed

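The 9 scanner files were read as written by Agilent Feature Extraction 10.5.1.1 for the whole human genome 4x44K design 014850. Per the file headers, the processed signal is an intensity, background-subtracted and detrended within each array and not scaled between arrays; the mean spot signal and the median local background, also read, are intensities per the file headers. Each file held 45015 spots, 43376 of them not controls, with 70 to 145 spots per array, controls aside, flagged as outliers in their own signal and 0 saturated. Spots printed at least 5 times and well above background had a median SD of 0.05 to 0.06 (log2) between their copies. The 75th percentile of the processed signal was 843 to 1236. Control spots and these flagged spots were dropped, the log2 of the processed signal was averaged over the spots of a probe, and each array's 75th percentile was subtracted on the log2 scale.

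Of 41000 probes, 217 were dropped because no unflagged spot was left on at least 1 array. Probe names were matched to current symbols by accession (23576), symbol (2789) or synonym (1122), and 13296 kept the name in the file. Each of 30365 genes was read by its probe of highest mean signal. Genes whose probe lay well above background on at least 4 of 9 arrays were tested, 19979 in all, of which 13043 had a gene symbol that was not a clone, a numbered locus or an uncharacterised frame. Probe positions are those of the hg18 annotation in the files. Where all arrays of a level lay at background, a change is given as a bound computed from the lowest signal called well above background on those arrays.

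The tests were made with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8). A single additive fit over 9 arrays held a control intercept, irradiated against control, and centred terms for radiation type, dose and time, with 4 residual degrees of freedom, 2.51 prior degrees of freedom and a median residual SD of 0.14. P-values were moderated and adjusted by Benjamini-Hochberg at 0.05 over all genes. Interaction terms were added singly, which left 3 residual degrees of freedom. The X-ray and proton arrays were each set against the control in the same fit. Standard errors are those of the moderated fit. The named-gene rule, the gene lists, the tests and the alternatives were chosen before the data were examined, except where stated. The rule named, for each contrast, up to 10 highest and 10 lowest symbols past the threshold with a single direction in every matched pair, up to 4 members of each list, and CDKN1A, MDM2, GDF15, FDXR and CCNB1; for single arrays it named the 5 highest and 5 lowest well above background on both arrays.

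Gene lists were tested with camera at the preset inter-gene correlation of 0.01 and again with a correlation estimated per list, adjusted over 22 pathway lists and, separately, over 7 cell-type lists. The estimate rests on the few residual degrees of freedom of the fit, so the second test is weak. A call lost there does not show that a list was unmoved, nor does the second test back the calls of the first. A gene of the rule and a pathway list are not reported here. The other pathway lists, with the number of tested genes, were G2/M and mitosis (46), G1/S and DNA replication (47), histones (41), NF-kB and inflammatory cytokines (23), interferon-stimulated genes (23), immediate early genes (28), unfolded protein and ATF4 response (32), heat shock (18), NRF2 and oxidative stress (27), hypoxia and glycolysis (27), cholesterol synthesis (24), double-strand break repair (38), base and nucleotide excision repair (32), apoptosis regulators (35), TGF-beta, EMT and matrix (31), angiogenesis and migration (35), metallothioneins (11), senescence-associated genes (18), ribosomal proteins (42), mitochondrial respiration (32) and housekeeping genes (20). The cell-type lists were ductal epithelial (10), acinar (4), fibroblast and stellate (5), leukocyte (7), endothelial (4), neuroendocrine (7) and erythroid (3) markers. For single arrays the median of a list was set against 10000 random lists drawn from the same 20 bins of mean expression, and genes were counted at 2-fold without a test. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

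The fit was run first on simulated arrays with the observed spread, independent noise and no slide or interaction effects. It recovered 4.48%, 67.2% and 97.0% of genes changed by 0.5, 1 and 2 (log2) for irradiated against control, 52.2%, 91.0% and 100% for proton against X-ray, 44.8%, 89.6% and 100% for 8 Gy against 2 Gy, and 43.3%, 88.1% and 100% for 12 h against 3 h, with 8 to 13 false calls among 123 to 175.

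The alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, a filter requiring all 9 arrays, a variance trend, every probe tested separately, leaving out each irradiated array, slide as a fixed block, the deposited value table, the 8 irradiated arrays alone, no matching on the other factors and all 3 two-way interactions kept. Slide as a random block (consensus correlation 0.338), the X-ray and proton contrasts against the control, list tests of the interactions, the control's slide alone, list tests with a fixed slide block at the preset and at an estimated correlation, and normexp without outlier-flagged spots in its fit (637 to 2210 spots per array, controls included, flagged in their own signal or in their local background) were added after the data were seen. List tests with slide as a random block used the form of camera that takes the moderated t-statistics, at the preset correlation alone. Radiation type has no value with slide as a fixed block. Time is read there only on the control's slide, where X-ray 2 Gy 12 h is the only 12 h array. That fit also leaves fewer residual degrees of freedom than the main fit.

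The deposited value table is in log2 units, as its values follow the scaled log2 signal of the same array at r = 0.996 to 0.998. The scaled signal is the log2 processed signal after the array's scaling percentile was subtracted. The slope was 0.973 to 0.990, and the offset of 9.67 to 10.2 includes the subtracted percentile. The deposited value table held 3623 probes, 3618 of them complete, with 0 values missing among those. The deposited column medians (log2) were 7.73 for the control, 7.78, 7.75, 7.94 and 7.94 for X-rays at 2 Gy 3 h, 8 Gy 3 h, 2 Gy 12 h and 8 Gy 12 h, and 7.52, 7.41, 8.12 and 8.23 for protons in that order, so the columns were neither centred nor scaled to a common percentile. Higher values mean higher signal. Its normalization and the rule that chose its probes are not given in the sources used here, nor are the time of the control, the number of cultures or the steps between irradiation and RNA isolation. 0 other columns entered the tests.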

Results

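The series measured gene expression in MIAPaCa-2, an established pancreatic carcinoma cell line, after proton or X-ray irradiation. Cy3-dyed RNA was hybridised to 9 single-colour Agilent whole human genome arrays. There was 1 array of non-irradiated cells and 1 array for each of 8 conditions, which combined proton or X-ray irradiation, a dose of 2 or 8 Gy, and RNA isolation 3 or 12 h later. Each condition had n = 1. The p-values therefore came from a fit over all 9 arrays and measured only the spread between these arrays around additive effects, not the spread between cultures, and the number of arrays limited the precision of every interval. Between 64.0% and 69.4% of probes lay well above background on each array, and 19979 genes were tested. Values are log2 differences with standard errors (SE).

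The arrays fell on 4 slides. The control shared a slide with the X-ray arrays at 2 Gy 3 h, 8 Gy 3 h and 2 Gy 12 h, and the X-ray array at 8 Gy 12 h lay on another slide. The proton arrays at 3 h shared a slide, as did those at 12 h. No slide held both radiation types, so radiation type and slide cannot be told apart in any comparison of protons with X-rays. E1A spike-in probes, which read RNA added at the bench in place of cellular RNA, stood 4.00 to 7.66 times above the 75th percentile on the 4 proton arrays and 3.05 to 3.36 times on the 4 X-ray arrays. The means were 5.09 ± 1.72 (SD, n = 4) and 3.20 ± 0.128 (SD, n = 4), with a two-sided exact permutation p = 0.0286, the smallest p this design allows. No other split into 4 and 4 keeps the slides whole, so this p does not set radiation type apart from slide; the control array read 3.41. On the first principal component, which held 48.9% of the variance, the 4 proton arrays lay between 27.9 and 42.5 and the other 5 arrays between -31.7 and -25.2. The second component held 19.6% and separated 3 h from 12 h among the irradiated arrays. Across genes, which are not independent replicates, the control array correlated with the X-ray arrays at r = 0.993 to 0.997 and with the proton arrays at r = 0.987 to 0.989.

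**Figure D1:**
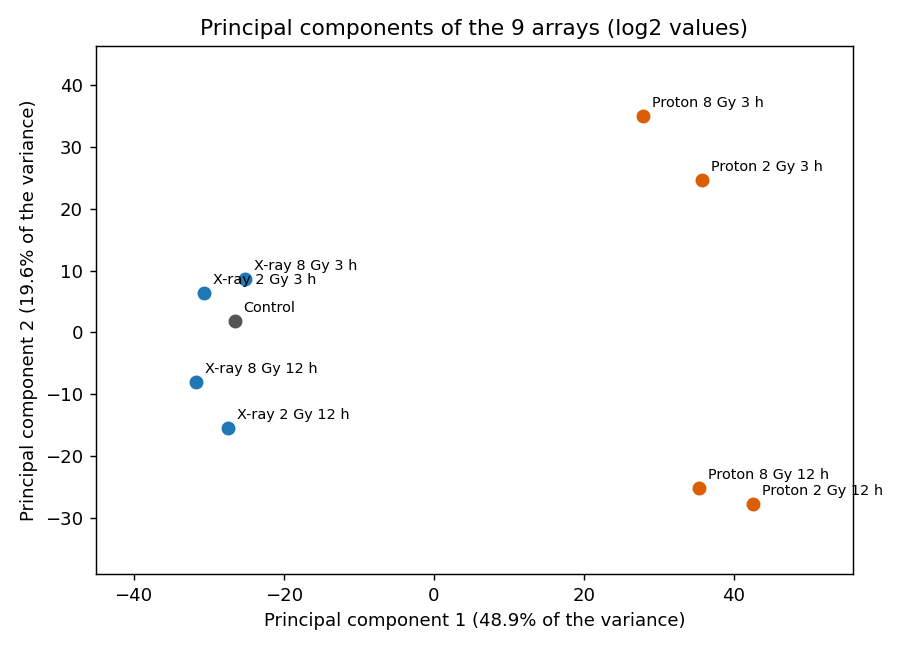
Principal components 1 and 2 of the 9 arrays over 19979 genes (log2 values, unitless scores), 1 point per array, coloured by radiation type. The 4 proton arrays lie between 27.9 and 42.5 on component 1, and the control lies among the X-ray arrays.

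For irradiated against control, which asked what irradiation moved whatever its kind, the zinc finger transcription factor gene ZBTB7C fell by 2.58 (SE 0.13, adjusted p = 0.00764) and differed by -2.81 to -2.42 over the irradiated arrays. All 8 differences share the single control array, so an odd reading on it would give the same picture. Its probe lies on chromosome 18, at 43810194 to 43810253 of hg18. The nuclear receptor gene PPARG (chromosome 3, 12433499 to 12433558) fell 2.30-fold (SE 0.10 on the log2 scale, adjusted p = 0.0484). Most of that fall lay in the proton arrays: PPARG was -2.11 in proton against control (adjusted p = 0.00262) and -0.29 in X-ray against control (adjusted p = 0.969), while ZBTB7C was -2.59 and -2.57. POM121L9P, a transcribed pseudogene whose copies share sequence, rose; its control signal was not above background, so the rise on the processed signal was at least 1.23-fold. The POM121L9P call was lost with quantile normalization, a variance trend, a fixed slide block and both forms of normexp; it was 0.28 under normexp without outlier-flagged spots, where ZBTB7C was -1.97. The other 2 of 5 calls, both lower, were probes without a gene symbol. Among the 4 arrays of the control's own slide, which took part in the fit, ZBTB7C was -2.58 and PPARG -0.23. With slide as a fixed block limma called 0 genes, as with normexp; with slide as a random block it called 10, and with no filter on dim probes 127. The count was 0 without X-ray 2 Gy 12 h or proton 8 Gy 3 h, 1 without proton 2 Gy 3 h, proton 2 Gy 12 h or proton 8 Gy 12 h, 3 without X-ray 2 Gy 3 h and 8 without X-ray 8 Gy 3 h.

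Among genes that respond to DNA damage, PHLDA3 was 0.84 higher (SE 0.27), PMAIP1 0.83 (SE 0.19) and the mitochondrial reductase gene FDXR 0.67 (SE 0.11, adjusted p = 0.12) in irradiated against control, and none of these passed. FDXR differed by 0.31 to 0.93 over the irradiated arrays, against the same control array. CDKN1A (0.42, SE 0.25), MDM2 (0.55, SE 0.21), GDF15 (0.44, SE 0.17) and CCNB1 (-0.32, SE 0.19) did not pass, and another CDKN1A probe had the opposite sign (-0.97). G2/M and mitosis genes were lower, with 7 of 46 higher (median -0.19, adjusted p = 1.98e-04; adjusted p = 0.96 with an estimated correlation), and so were cholesterol synthesis genes, with 3 of 24 higher (median -0.24, adjusted p = 8.77e-05; adjusted p = 0.96 with an estimated correlation). On the control's slide the medians were -0.05 for G2/M genes and 0.08 for cholesterol genes. With slide as a fixed block they were -0.04 and 0.09, and neither list passed there. Both comparisons set the control against X-ray arrays alone, while the cholesterol median was -0.51 in proton against control and 0.05 in X-ray against control, so they leave the proton decrease untested within slides. Without a slide term the other lists named here did not pass; with the fixed block histone genes (median -0.15) and TGF-beta, EMT and matrix genes (median -0.17) moved down and interferon-stimulated genes up (median 0.12), and all 3 were lost there with an estimated correlation (adjusted p = 0.97).

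The proton arrays held most departures from the control. The fit called 2507 genes for proton against control, 1437 up and 1070 down, and 2 genes for X-ray against control, both down; ZBTB7C was among both. The difference between these counts is the proton against X-ray contrast itself. It depended on the settings: normexp called 0 genes for either, and no filter on dim probes gave 736 for protons and 86 for X-rays. In proton against control the orphan nuclear receptor gene NR4A1 rose by 3.39 (SE 0.48, adjusted p = 0.0141), PMAIP1 rose by 1.34 (SE 0.20, adjusted p = 0.0151), FDXR rose by 0.87 (SE 0.12, adjusted p = 0.0127), and the collagenase gene MMP1 fell by 2.22 (SE 0.17, adjusted p = 0.0038). In X-ray against control none of these passed, at 1.05 for NR4A1, 0.33 for PMAIP1, 0.48 for FDXR and -0.34 for MMP1. The control shared a slide with X-ray arrays alone, and 1213 proton calls were made with slide as a random block. The proton count was 622 without proton 2 Gy 12 h, 967 without X-ray 2 Gy 12 h, 979 without proton 8 Gy 12 h, 1269 without proton 2 Gy 3 h, 1468 without X-ray 2 Gy 3 h and 1624 without X-ray 8 Gy 12 h.

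For proton against X-ray, the question in the series title, the largest changes went both ways. CD86, a co-stimulatory receptor gene, rose by 3.61 (SE 0.48), NR4A3 by 3.06 (SE 0.61), the AP-1 gene FOSB by 2.82 (SE 0.47) and NR4A1 by 2.34 (SE 0.30, adjusted p = 0.00279). SPATA13, the kinase regulator gene PIK3R3, the DNA demethylase gene TET2 and SYT1 rose by 2.27, 2.25, 2.15 and 2.01. The nucleotide receptor gene P2RY6 fell by 3.86 (SE 0.22), the lipid transporter gene ABCA6 by 3.36 (SE 0.10), AFAP1L2 by 2.69 and TSC22D3 by 2.42. NR4A3, P2RY6, ABCA6 and TSC22D3 lay at background on some arrays, so the sizes are uncertain: they were 1.26, -1.29, -1.24 and -0.92 under normexp without outlier-flagged spots. There CD86 was 2.66, FOSB 2.11, TET2 1.18 and AFAP1L2 -2.07. PTX3, which encodes a secreted pentraxin, fell by 2.68 (SE 0.07, adjusted p = 1.15e-04), lower in 4 of 4 matched pairs. CP, MMP3, FDCSP, ABCA8 and ECSCR were not above background on any proton array and were, on the processed signal, at least 3.06-fold, 4.76-fold, 2.80-fold, 2.76-fold and 1.82-fold lower. Under normexp without outlier-flagged spots they were only -0.54, -0.68, -0.46, -0.38 and -0.30. CELF6 and CCR3 rose by 2.58 and 2.25 and took the other sign under normexp background correction, and they were 0.79 and 0.68 without outlier-flagged spots in its fit. In all, limma called 7464 of 19979 genes, 3716 up and 3748 down, 823 of them at least 2-fold.

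With normexp limma called 368 genes for proton against X-ray and with no filter on dim probes 4724. A random slide block called 4304 genes, all 4304 among the 7464. No slide held both types, and this block applied a single correlation to all genes. It therefore cannot take a slide effect out of this contrast. The count was 4414 without the proton 2 Gy 12 h array and 4685 without the X-ray 2 Gy 12 h array. At matched dose and time, 1073 to 1407 genes were at least 2-fold apart between single arrays.

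Histone genes rose with protons: 30 of 41 rose and 3 fell (33 and 4 adjusted over the list alone), with a median of 0.52 (adjusted p = 1.74e-08; adjusted p = 0.54 with an estimated correlation). H4C4 rose by 1.14 (SE 0.12) and H4C2 by 1.06 (SE 0.12); histone coding sequences resemble each other, so a probe may read several copies. Of the cholesterol synthesis genes 19 of 24 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -0.53 (adjusted p = 1.74e-08; adjusted p = 0.60 with an estimated correlation). DHCR7, the last enzyme of the pathway, fell by 1.21 (SE 0.11), FDFT1 by 0.99 (SE 0.08) and MVK by 0.83 (SE 0.07). Base and nucleotide excision repair genes moved down, with 16 of 32 lower and 1 higher (17 and 1 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation): the glycosylase gene NEIL2 fell by 0.89 and APEX1 by 0.73, while 2 probes of the ligase gene LIG3 read -0.76 and 0.50. Of 153 named gene contrasts with at least 2 probes, 33 had probes of opposite sign. Of the interferon-stimulated genes 12 of 23 fell and 1 rose (14 and 1 adjusted over the list alone; adjusted p = 0.84 with an estimated correlation), with HERC5 at -2.28, OASL at -1.60 and OAS1 at -1.38; HERC5 and OAS1, at background on some proton arrays, were -0.50 and -0.36 under normexp without outlier-flagged spots. Of the immediate early genes 11 of 28 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.95 with an estimated correlation).

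Cell cycle genes moved down as lists with protons, although single members rose. Of the G2/M and mitosis genes 15 of 46 fell and 2 rose (20 and 2 adjusted over the list alone), CDC25C by 0.68 (SE 0.06) and the kinase gene AURKB by 0.61 (SE 0.10). Of the G1/S and DNA replication genes 17 of 47 fell and 4 rose (21 and 4 adjusted over the list alone), UNG among the former and the checkpoint gene CLSPN (0.96, SE 0.15) among the latter. Of the mitochondrial respiration genes 9 of 32 fell (7 adjusted over the list alone). Each of these 3 calls was lost with an estimated correlation (adjusted p = 0.95) and with quantile normalization, which kept 5 of the 8 lists. Under normexp the direction of all 3 tests turned upward without passing, and the excision repair list was lost (adjusted p = 0.12). With slide as a random block the G1/S and mitochondrial lists missed the threshold (adjusted p = 0.098 for both) and the other 6 passed. Their medians were 0.52 for histones, -0.52 for cholesterol synthesis, -0.23 for excision repair, -0.35 for interferon-stimulated genes, 0.43 for immediate early genes and -0.23 for G2/M genes. A random block does not set radiation type apart from slide, so it cannot say which of them moved these lists.

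Of the genes followed in every contrast, FDXR rose with protons by 0.39 (SE 0.07) and the ubiquitin ligase gene MDM2 rose 2.15-fold (SE 0.14 on the log2 scale, although -0.10 under normexp), while GDF15 fell by 0.52 (SE 0.11) and CCNB1 by 0.43 (SE 0.13), a call lost with quantile normalization, with no filter on dim probes, with normexp, with slide as a random block and in the deposited value table. CDKN1A did not pass (0.23, SE 0.17, adjusted p = 0.32), and the apoptosis gene PMAIP1 rose by 1.00 (SE 0.12). Double-strand break repair genes split, with XRCC2 up by 1.30 (SE 0.15) and CHEK2 down by 0.78 (SE 0.10), 5 of 38 risen and 8 fallen. Apoptosis regulators (5 risen and 10 fallen of 35) included the death ligand gene TNFSF10, down by 1.67 (-0.75 under normexp without outlier-flagged spots). TGF-beta, EMT and matrix genes (8 and 8 of 31) included MMP1, down by 1.88, and ID2, up by 1.59, and angiogenesis and migration genes (7 and 11 of 35) included CXCR4, up by 1.46. These 4 lists did not pass. NF-kB and inflammatory cytokine genes (4 and 3 of 23), unfolded protein and ATF4 response genes (2 and 3 of 32), heat shock genes (1 and 4 of 18), NRF2 and oxidative stress genes (5 and 5 of 27), hypoxia and glycolysis genes (0 and 8 of 27), senescence-associated genes (3 and 4 of 18), ribosomal protein genes (0 and 2 of 42), metallothionein genes (1 and 0 of 11, with probes that may read several copies) and housekeeping genes (3 and 6 of 20) did not pass as lists either, with adjusted p between 0.07 and 0.94.

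**Figure D2:**
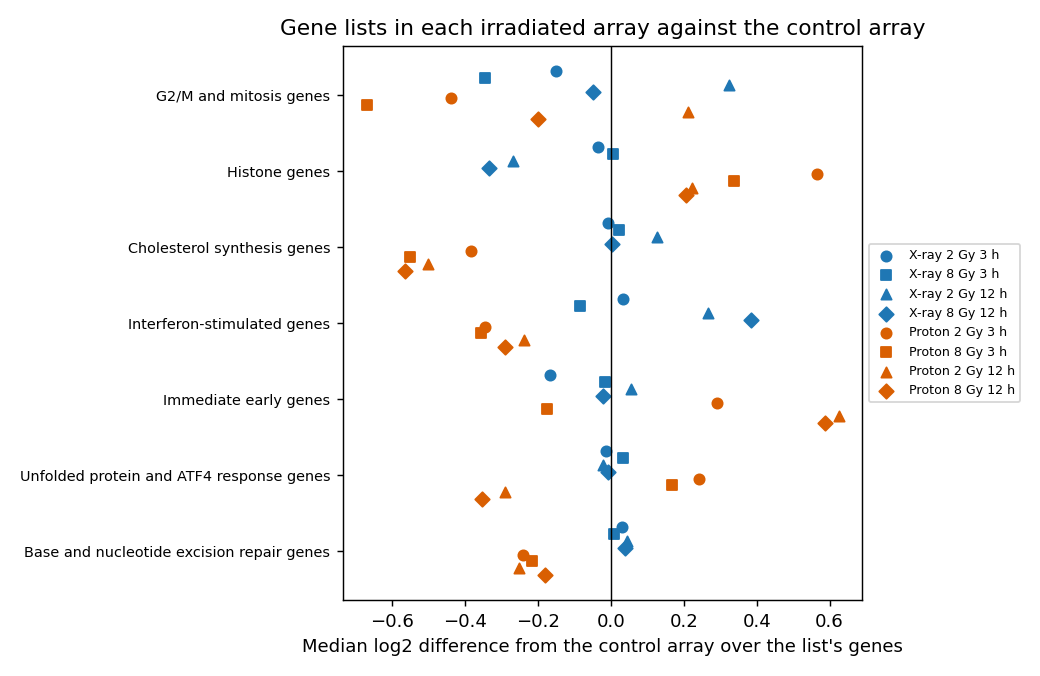
Median log2 difference from the control array over the members of 7 gene lists (x axis), 1 point for each of the 8 irradiated arrays, coloured by radiation type and shaped by dose and time. Cholesterol synthesis medians lie between -0.57 and -0.38 on the proton arrays and between -0.01 and 0.13 on the X-ray arrays.

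For 8 Gy against 2 Gy, mitotic genes were lower at the higher dose. None of the 46 G2/M and mitosis genes was higher (median -0.32, camera adjusted p = 3.74e-38; adjusted p = 0.38 with an estimated correlation), and 30 fell adjusted over the list alone. The mitotic kinase gene AURKA was -0.65 (SE 0.09), lower in 4 of 4 matched pairs by -0.73 to -0.59, KIF20A was -0.59 (SE 0.18), and the centromere histone gene CENPA was -0.54 (SE 0.12). G1/S and DNA replication genes were higher in 42 of 47 cases (median 0.13, adjusted p = 1.17e-09; adjusted p = 0.63 with an estimated correlation), and 1 rose adjusted over the list alone. The cyclin gene CCNE2 was 0.58 higher (SE 0.06), in 4 of 4 pairs by 0.54 to 0.63. Within the 3 slides that held both doses, G2/M medians were -0.23 for X-rays at 3 h, -0.23 for protons at 3 h and -0.39 for protons at 12 h. G1/S medians on these slides were 0.01, 0.13 and 0.20, and with slide as a fixed block the medians were -0.27 for G2/M and 0.11 for G1/S. AURKA was -0.63, -0.59 and -0.73 on these slides, and CCNE2 was 0.63, 0.54 and 0.59.

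Histone, heat shock and cholesterol synthesis lists also passed downward at 8 Gy, with medians of -0.07, -0.10 and -0.07 (adjusted p = 9.55e-05, 0.00248 and 0.024; adjusted p = 0.78, 0.78 and 0.94 with an estimated correlation). The heat shock and cholesterol calls were lost with slide as a fixed block (medians -0.05 and -0.02, adjusted p = 0.087 and 0.23), and histones passed there (median -0.06). In the X-ray 3 h pair all 3 medians lay on the other side of 0, at 0.02, 0.04 and 0.04. They were -0.20, -0.11 and -0.14 in the proton 3 h pair and -0.01, -0.11 and -0.05 in the proton 12 h pair. No single gene passed over all genes: limma called 0 genes at an adjusted p under 0.05, and the lowest adjusted p was 0.89. In the same test 1076 had an unadjusted p under 0.05 where 999 would by chance. The additive fit left radiation type by time in its error, a term with 4151 genes at an unadjusted p under 0.05. A number near 999 therefore does not show that dose moved no single gene. The receptor gene EPHB3 was 0.79 higher (SE 0.21) and MYOM1, LHFPL5, STON1 and ADAD2 were 0.73 to 0.87 higher, while RUNX1-IT1, NAV2, SNORD14E, the helicase gene PIF1 and CPXM1 were -0.85 to -0.67. CCNB1 was -0.40 (SE 0.13), and CDKN1A (0.01), MDM2 (-0.11), GDF15 (-0.10) and FDXR (-0.00) lay near 0. On simulated data the same fit recovered 44.8% of genes changed by 0.5 and 89.6% of genes changed by 1 on the log2 scale. Those data held no slide or interaction effects, so the shares may not carry over to the real arrays.

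For 12 h against 3 h, mitotic genes rose. CENPA rose by 1.53 (SE 0.12, adjusted p = 0.00929), its loading factor HJURP by 1.51, the spindle genes TROAP and BORA by 1.56 and 1.47, PIF1 by 2.06 (SE 0.24), and ARHGEF39 and MEGF6 by 1.49 and 1.46. RGS9 and DISC1 were at least 2.62-fold and 2.45-fold higher, BTBD8 rose by 1.48, and all 3 took the other sign under normexp. NR4A3 fell by 3.83 (SE 0.61), although it lay above background on 1 of the 4 arrays at 12 h and was -1.52 under normexp without outlier-flagged spots. Also lower were the interleukin receptor gene IL6R, which fell by 1.91 (SE 0.27), the NF-kB subunit gene RELB, by 1.42 (SE 0.20), and the receptor gene TNFRSF9, by 1.38 (SE 0.22). ST3GAL1, EFNB2, KRT16, RAB7B and LIMS3, which has near-identical copies, fell by 1.45, 1.28, 1.25, 1.24 and 1.90, and 2 probes of WHRN read -1.28 and 0.23. Under normexp without outlier-flagged spots RGS9 was 0.21, DISC1 0.08, BTBD8 0.38, IL6R -1.23, TNFRSF9 -0.55, ST3GAL1 -0.54 and LIMS3 -1.22. Over that setting, quantile normalization, both filters and a random slide block, MEGF6 ranged from 0.85 to 1.47 and EFNB2 from -1.28 to -0.75. The fit called 1271 genes, 660 up and 611 down, 96 at least 2-fold. Within the X-ray 2 Gy pair, which shared a slide and took part in the fit, CENPA was 1.13 higher, PIF1 1.32 higher and RELB -0.87.

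The time count rested on single arrays. It was 0 without any 1 of the 4 proton arrays, 22 without X-ray 8 Gy 12 h, 104 without X-ray 2 Gy 12 h, 473 without X-ray 8 Gy 3 h and 727 without X-ray 2 Gy 3 h. For 12 h against 3 h limma called 0 genes with slide as a fixed block, 0 with no filter on dim probes, 0 with normexp and 364 with slide as a random block, all 364 among the 1271. The fixed block read time from the X-ray 2 Gy 12 h array alone, with fewer residual degrees of freedom than the main fit. Its count of 0 therefore does not show that the time effect vanished within slides.

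As lists, 27 of 46 G2/M and mitosis genes rose at 12 h and 0 fell (38 and 0 adjusted over the list alone; median 0.57, adjusted p = 1.74e-25; adjusted p = 0.61 with an estimated correlation), among them the kinesin gene KIF18A by 1.09 (SE 0.07) and FAM83D by 1.17 (SE 0.10). The within-slide X-ray 2 Gy median was 0.48, with 45 of 46 members higher, and the fixed-block median was 0.46. For every list these 2 values rest on the same X-ray 2 Gy 12 h array, so they are not separate checks. Histone genes fell in 14 of 41 cases (15 adjusted over the list alone; median -0.14), H2AC6 by 0.82, with a within-slide median of -0.17 and -0.16 in the fixed block. Interferon-stimulated genes rose in 5 of 23 cases (7 adjusted over the list alone; median 0.12), DDX60 by 0.70 and IRF9 by 0.62, with 0.30 within slide and 0.32 in the fixed block. The medians of this list were 0.30 and 0.51 in the X-ray pairs at 2 and 8 Gy, and -0.13 and 0.02 in the proton pairs; DDX60 was -0.30 under normexp. Double-strand break repair genes (5 of 38 risen, 9 adjusted over the list alone) and immediate early genes (4 of 28 risen, 12 adjusted over the list alone) moved up, with medians of 0.15 and 0.27 and within-slide medians of 0.03 and 0.17; with slide as a fixed block neither passed (medians 0.07 and 0.13). These calls had adjusted p between 0.61 and 0.74 with an estimated correlation, and the histone and interferon calls were lost with normexp.

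Unfolded protein and ATF4 response, NRF2, ribosomal protein, hypoxia and angiogenesis lists moved down at 12 h, with medians of -0.21, -0.16, -0.12, -0.20 and -0.17 and within-slide X-ray medians of 0.04, -0.07, -0.05, -0.02 and -0.03. Under a fixed slide block, which read time from the same X-ray 2 Gy 12 h array, these 5 lists did not pass, at -0.00, -0.06, -0.02, -0.02 and -0.02. Cholesterol synthesis genes moved up there (median 0.13) and G1/S genes down (median -0.12), 2 calls lost there with an estimated correlation (adjusted p = 0.84). The hypoxia list was also lost with slide as a random block and with quantile normalization, and the ribosomal list with quantile normalization. All 5 were lost with normexp and with an estimated correlation (adjusted p = 0.74 with an estimated correlation). The amino acid transporter gene SLC7A5 fell by 0.82 (SE 0.13) and the vasodilator peptide gene ADM by 0.75 (SE 0.09). CDKN1A (-0.56, SE 0.17, adjusted p = 0.093), MDM2 (-0.23), GDF15 (0.22), FDXR (0.21) and CCNB1 (0.17) did not pass, whereas the cyclin gene CCNG2 rose by 1.24 (SE 0.14) and PMAIP1 fell by 0.66 (SE 0.12). The other pathway lists named here did not pass.

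**Figure D3:**
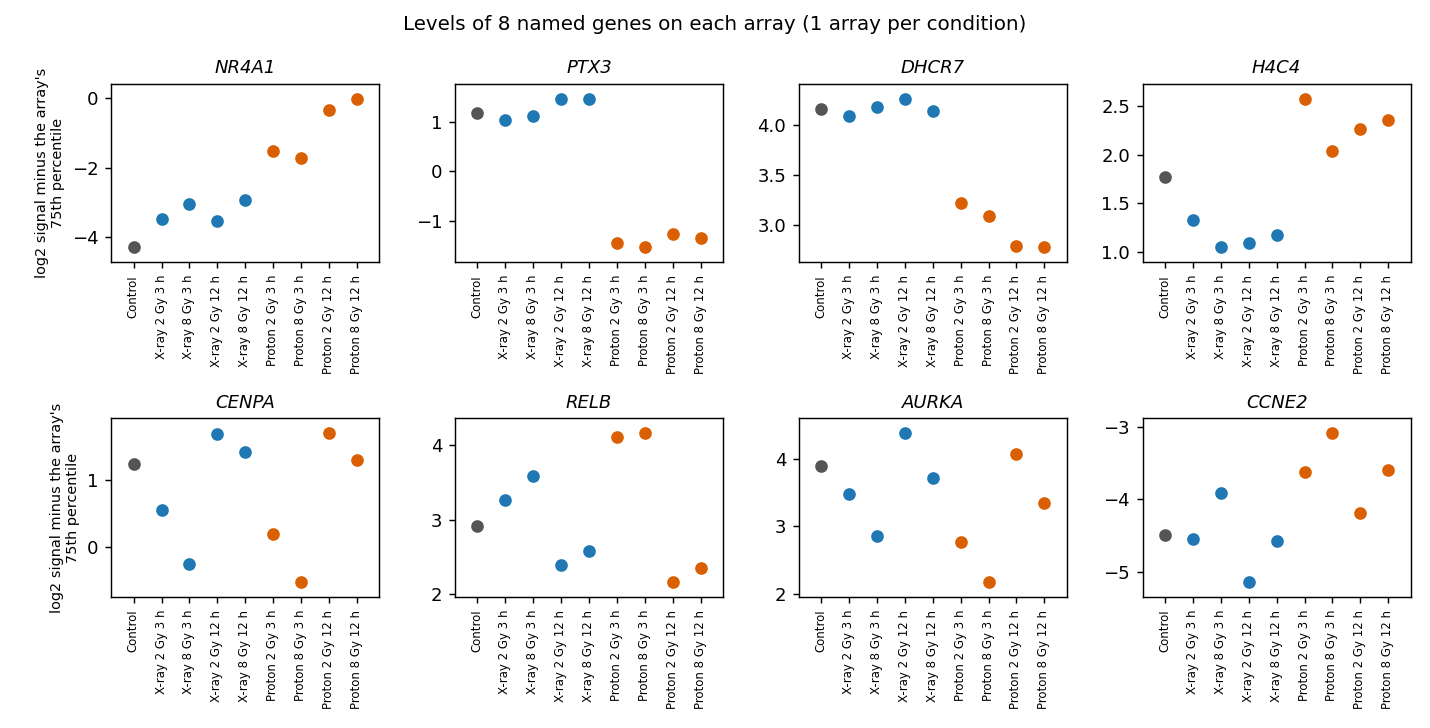
Levels of NR4A1, PTX3, DHCR7, H4C4, CENPA, RELB, AURKA and CCNE2 on each of the 9 arrays (y axis: log2 signal minus the array's 75th percentile; 1 point per array, n = 1 per condition, coloured by radiation type). The 4 proton points of PTX3 and DHCR7 lie below all X-ray points, and the 8 Gy points of AURKA lie below the 2 Gy points of the same type and time.

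Whether 1 factor changed the effect of another was tested with interaction terms in limma. No gene passed. For radiation type by time 0 genes were called, with 4151 at an unadjusted p under 0.05 where 999 would by chance (lowest adjusted p = 0.123). For radiation type by dose (282) and dose by time (508) 0 were called, and both numbers lay below the 999 of chance. Each term was added alone, so differences of radiation type by time stayed in the error of the other 2 fits. Those counts of 0 therefore do not show that such interactions were absent. With a variance trend radiation type by time called 281 genes, and under normexp without outlier-flagged spots 1272, so its count of 0 depended on the settings. Since the proton times lay on different slides this term cannot be told apart from slide either. Across genes, the time effect in X-ray arrays correlated with that in proton arrays at r = 0.31, the dose effect at r = 0.22, the radiation type effect at 3 h with that at 12 h at r = 0.65 and at 2 Gy with that at 8 Gy at r = 0.84. The time effect correlated at r = 0.61 between doses and the dose effect at r = 0.21 between times. The dose values turned to -0.016 between types and -0.057 between times with no filter on dim probes, and to -0.36 and -0.88 with normexp, where the time effect between doses was -0.40. Genes are not independent replicates, so these values have no p. The 2 sets of arrays behind each value were disjoint. Sets split by radiation type shared no slide, whereas sets split by time or by dose did. For example, proton time effects at both doses set the same 2 slides against each other, so a slide effect alone would raise that r.

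Single conditions were set against the control array as values with no replicate check. All 8 share that array, so a gene with an odd control value recurs in each of them. ZBTB7C was among the 5 lowest in 7 arrays, and EPHB3 was among the 5 highest on the X-ray arrays at 8 Gy 3 h (1.54), 2 Gy 12 h (1.53) and 8 Gy 12 h (2.18). On the proton arrays at 12 h the AP-1 gene FOS was 5.27 higher at 2 Gy and 5.58 at 8 Gy, NR4A1 was 3.93 and 4.27 higher and FOSB 3.70 and 3.73. On the proton arrays at 3 h NR4A1 was 2.78 and 2.57 higher, the Notch target gene HEY1 2.49 and 2.50, and PTX3 -2.63 and -2.72. Counts at least 2-fold apart were 336, 216, 252 and 595 for X-rays at 2 Gy 3 h, 8 Gy 3 h, 2 Gy 12 h and 8 Gy 12 h, and 1164, 1313, 1486 and 1332 for protons in that order. Cholesterol synthesis medians stood at percentile 0 of 10000 random lists of like expression on all 4 proton arrays and between the 6.96th and 99.9th on the X-ray arrays.

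Marker lists of other cell types showed no shift past the threshold in any of the 4 contrasts, with the lowest adjusted p at 0.247. Single markers did pass for proton against X-ray: 0 rose and 3 fell of 10 ductal markers, 2 and 1 of 5 fibroblast markers, 1 and 3 of 7 leukocyte markers, 0 and 1 of 4 endothelial markers and 1 and 0 of 7 neuroendocrine markers. COL3A1 was -1.21 (-0.55 under normexp without outlier-flagged spots), CD68 -0.80, KRT8 -0.49, ENG -0.39 and COL1A2 0.37. These 5 passed in 5 of 5 alternatives: quantile normalization, both filters, slide as a random block and normexp without outlier-flagged spots. None of these alternatives sets radiation type apart from slide. Other marker calls were lost in some of them. LAPTM5, the leukocyte marker that rose, passed in 0 of 4, CD4 in 1 of 5, and CD8A and CHGB in 2 of 5. ACTA2 and CLDN4 passed in 3 of 5 and KRT18 in 4 of 5. For 12 h against 3 h 1 rose and 1 fell of the ductal and 1 rose of the neuroendocrine markers. Their proton against X-ray medians were -0.07 for pancreatic ductal epithelial, 0.10 for acinar, 0.31 for fibroblast and stellate, -0.20 for leukocyte, -0.48 for endothelial, 0.03 for neuroendocrine and 0.22 for erythroid markers. The keratin gene KRT18 was the highest ductal marker (7.45 above the 75th percentile on the log2 scale), COL1A2 the highest fibroblast marker (3.43) and CD4 the highest leukocyte marker (2.25). No acinar, endothelial, neuroendocrine or erythroid marker exceeded 0.13. The lists hold 3 to 10 tested genes, and the cell line itself may express any of them.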

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

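All tests in this part were chosen after the data were seen, and 66 list tests (22 for each of 3 interactions) stand behind the list results. The list results were picked out because the effect of 1 factor differed between the levels of another in a camera test with the preset correlation. None held with an estimated correlation, where adjusted p lay between 0.222 and 0.984.

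Between protons and X-rays the change from 3 h to 12 h differed for 11 lists. The median differences of effects (proton minus X-ray) were 0.48 for immediate early genes, 0.24 for G2/M and mitosis genes, 0.14 for double-strand break repair genes and 0.048 for heat shock genes. They were -0.46 for unfolded protein and ATF4 response genes, -0.42 for interferon-stimulated genes, -0.25 for hypoxia and glycolysis genes, -0.22 for cholesterol synthesis genes, -0.22 for angiogenesis and migration genes, -0.21 for ribosomal protein genes and -0.18 for NRF2 and oxidative stress genes. The 2 proton times lay on different slides, so radiation type by time cannot be told apart from slide.

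Between protons and X-rays the effect of dose differed for mitochondrial respiration genes (0.11). Between 12 h and 3 h the effect of dose differed, among the lists reported here, for G1/S and DNA replication genes (0.14), G2/M and mitosis genes (-0.093) and histone genes (0.031).

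The E1A spike-in probes, which no comparison of the report tests for genes, stood above the control array's 3.41 on each proton array: 4.49 at 2 Gy 3 h, 7.66 at 8 Gy 3 h, 4.00 at 2 Gy 12 h and 4.22 at 8 Gy 12 h, as multiples of the array's 75th percentile. Each condition had a single array, so no array could be set against others of its own condition.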

How the results depend on the processing

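The random slide block, the list tests with a slide term, the X-ray and proton contrasts against the control, and normexp without outlier-flagged spots were chosen only after the results were seen. The number of genes called depended strongly on the settings for irradiated against control and for 12 h against 3 h, and less for proton against X-ray. 8 Gy against 2 Gy, radiation type by dose and dose by time called 0 genes under all alternatives run. No paired analysis was possible because any 2 conditions shared a single replicate number; across conditions, arrays were matched on the other factors in the fit, and slide as a fixed block compared arrays within slides. Between 64.0% and 69.4% of probes lay well above background, which limits what can be said of weakly expressed genes. Of the named-gene values, 480 of those tested with quantile normalization kept their direction and side of the threshold, as did 460 with slide as a random block, 473 with a variance trend, 466 with normexp without outlier-flagged spots and 443 with the filter on all 9 arrays. With no filter on dim probes 430 did and 76 fell short. With normexp 310 did, 128 fell short, and 47 that had not passed and 21 that had passed changed sign. Under a fixed slide block, which called 0 genes in each contrast it allows, 278 did, 35 that had not passed changed sign and 62 fell short. No value could pass there, so the 278 are values that had not passed in the main fit either and lend no support to the calls. The other kept counts also include values that had not passed, so they do not count the calls that held. Most of the 310 kept with normexp had not passed in the main fit. Except where stated the cause was not tested.

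Leaving out 1 array at a time left 3 residual degrees of freedom and gave 0 to 8 genes for irradiated against control, 4414 to 7075 for proton against X-ray, 0 to 727 for 12 h against 3 h, 0 to 2 for X-ray against control and 622 to 2662 for proton against control. With the estimated correlation 0 lists passed for irradiated against control, 0 for proton against X-ray, 0 for 8 Gy against 2 Gy and 0 for 12 h against 3 h. With a fixed slide block added 0 passed for each of the 3 contrasts it allows. These tests had few residual degrees of freedom, so their counts of 0 do not show that no list moved. With slide as a fixed block irradiated against control called 0 genes and 12 h against 3 h called 0, 3 lists passed for 8 Gy against 2 Gy and 5 for 12 h against 3 h, and cholesterol synthesis genes turned to 0.089 for irradiated against control. The random slide block gave 10 genes for irradiated against control, 4304 for proton against X-ray, 364 for 12 h against 3 h and 1213 for proton against control. A variance trend gave 12 for irradiated against control, 2484 for 12 h against 3 h and 281 for radiation type by time. With no matching on the other factors 12 h against 3 h called 50, and with all 3 two-way interactions kept it called 0, with 1 residual degree of freedom in the latter case. Quantile normalization left 5 lists for proton against X-ray and 1 gene for X-ray against control.

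With the deposited value table irradiated against control called 19 genes, proton against X-ray 2456 and 12 h against 3 h 253. On the same 3544 genes the scanner values called 68, 2252 and 666. These genes held a larger share of calls than all 19979 did (7464 for proton against X-ray), so the counts do not carry over. PGK1 turned to 0.93 for proton against X-ray. Each source read a gene by its own brightest probe, so the probe of a gene may differ between them. With no filter on dim probes the counts were 127 for irradiated against control, 4724 for proton against X-ray, 0 for 12 h against 3 h, 86 for X-ray against control and 736 for proton against control. Single X-ray arrays at 2 Gy 3 h, 8 Gy 3 h, 2 Gy 12 h and 8 Gy 12 h then had 1013, 613, 672 and 1033 genes 2-fold from the control. The correlations across genes were -0.016 for dose effects between radiation types and -0.057 between times, both turned, 0.43 and 0.51 for radiation type effects between times and doses, and 0.30 for time effects between doses. With the filter on all 9 arrays irradiated against control called 11, and 115, 69, 84 and 308 genes were 2-fold from the control on the X-ray arrays in that order, 751 on proton 2 Gy 3 h, with 847 between the 2 Gy 3 h arrays of both types.

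With normexp, irradiated against control called 0 genes, proton against X-ray 368, 12 h against 3 h 0, X-ray against control 0 and proton against control 0, and 11 lists passed for irradiated against control. Genes 2-fold from the control numbered 89, 5838, 4836 and 64 on the X-ray arrays at 2 Gy 3 h, 8 Gy 3 h, 2 Gy 12 h and 8 Gy 12 h, and 271, 377 and 305 on the proton arrays at 2 Gy 3 h, 2 Gy 12 h and 8 Gy 12 h; between matched types they numbered 350 at 2 Gy 3 h, 181 at 8 Gy 3 h, 5436 at 2 Gy 12 h and 406 at 8 Gy 12 h. Correlations were 0.69 for time effects between types, -0.36 for dose effects between types, 0.79 for radiation type effects between times, -0.40 for time effects between doses and -0.88 for dose effects between times. For proton against X-ray the G1/S list turned to a test upward with a median of -0.052, as did G2/M at -0.10 and mitochondrial respiration at 0.065, and for 12 h against 3 h the ribosomal list turned, with a median of -0.0085. For proton against X-ray, genes turned to -0.30 (BRCA2), -0.67 (SMAD7), -0.72 (TNFAIP3), -0.046 (IPO8), -0.41 (POLR2A), -0.29 (CCNE2), -0.69 (LAPTM5), -0.093 (DNAJB4), -0.36 (CCN2), -0.24 (CELF6), -0.22 (EFNB2), -0.34 (CCR3), -0.25 (CHGB), -0.10 (MDM2) and -0.45 (CSF1). For 12 h against 3 h they turned to -0.23 (TNFSF10), -0.38 (RGS9), -0.49 (DISC1), -0.20 (BTBD8), -0.30 (DDX60) and -0.19 (HSPA1L). On single arrays PPP1R14C turned to 0.017 and TFAP2E to 0.15 (X-ray 2 Gy 3 h), MED18 to 0.25, FOXN4 to 1.15, MPIG6B to 1.02 and SEZ6 to 0.97 (X-ray 8 Gy 3 h), MPIG6B to 0.70, FOXN4 to 0.85, SEZ6 to 0.63 and GPR35 to 1.00 (X-ray 2 Gy 12 h), and LIPG to 0.012 (proton 8 Gy 3 h). Between matched arrays FLJ13224 turned to -0.43 at 8 Gy 3 h and GPR63 to -0.86 at 2 Gy 12 h.

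The normexp fit was part of these changes: its background mean ran from -352 to -9.03 across arrays, drawn by outlier-flagged spots as low as -8068. Once these were left out it ran from -14.4 to -8.35. Then 0 reported values that had passed changed sign, while 9 named-gene values and 7 list directions that had not passed did. The fit does not account for all changes, as counts of genes 2-fold from the control stayed below those of the main setting. Normexp without outlier-flagged spots gave 12 genes for irradiated against control, 1272 for radiation type by time and 5 for X-ray against control; 19 of the genes called for proton against X-ray and 40 of those for 12 h against 3 h took the other sign. Its offset shrinks differences of dim genes, and 31, 22, 15 and 71 genes were 2-fold from the control on the X-ray arrays at 2 Gy 3 h, 8 Gy 3 h, 2 Gy 12 h and 8 Gy 12 h, 298, 357, 403 and 330 on the proton arrays in that order, and 337, 306, 447 and 411 between matched types. The correlation of time effects between doses was 0.72.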

Other observations

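Among the tests below, the 3 split tests and the test of 2 probes per gene were written before the results were seen, and all others were chosen only after, as was the count of splits that divide the slides alike.

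The first pattern is the 7464 genes called for proton against X-ray. Of 33 splits of the 8 irradiated arrays into 4 and 4 that could be fitted, 1 called as many, the real one, and the highest other count was 0, but that bound ignored slides: 1 split, the real one, keeps every slide whole, so this test decides nothing. The spread of the difference across genes was 1.03 times as large at 8 Gy as at 2 Gy at 12 h and 0.916 times at 3 h. These values argue against growth with dose of the spread as a whole. It also holds any slide difference, present at both doses, so a smaller part that grows with dose could be hidden. The differences of 2 probes of a gene correlated at r = 0.475 over 4994 genes, between the bounds of 0.2 and 0.5 set beforehand. For 12 h against 3 h this r was 0.673 and for 8 Gy against 2 Gy 0.533, both higher. Single probes hybridising differently between slides therefore stay open as part of the pattern. The number of slides that held both types was 0, so slide or session in place of radiation type cannot be told apart from it, and the count is not evidence of a proton effect.

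The second pattern is the 1271 genes called for 12 h against 3 h. Of 33 splits 1 called as many, and the highest other count was 1, but 6 splits divide the slides as time does, too few for a share under 5%, so this test decides nothing. Of 256 genes 2-fold apart in both proton pairs, 215 (84.0%) had the same direction in the X-ray 2 Gy pair on a single slide, where 49.4% would without a relation, which argues against proton slides in place of time as the whole of the pattern. The median change of these genes was 1.36 in the proton pairs, which chose them, and 0.51 in the same direction in the X-ray 2 Gy pair. How much of the proton change belongs to slides was not measured and stays open.

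The third pattern is the lower level of G2/M and mitosis genes at 8 Gy than at 2 Gy, for which no gene passed alone; 33 of 33 splits called at least the 0 genes of the dose split, as any split must, so that test decides nothing. The highest median among the 3 dose pairs on a single slide was -0.23, with 42 to 46 of 46 members below 0 in the 4 pairs, which argues against slide in place of dose. After quantile normalization the list's median was set against the middle of 10000 random lists of the same mean expression. It differed by -0.416 to -0.219 over the 4 dose pairs and stood at percentile 0 in each. These values argue against the scaling of the arrays. Dose itself stays open: 4 pairs cannot give a two-sided exact sign p under 0.125. The list was also lost with an estimated correlation, a weak test with 4 residual degrees of freedom.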
